A study of Mus musculus with 9 samples.

How the data were processed

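The series holds 9 samples from the thymus of adult female mice: 3 RNA libraries, 3 T cell receptor (TCR) libraries and 3 hashtag samples, one of each per sorted population. Thymocytes of wild-type (WT) mice and of mice with the I173A substitution in CD3ε, a signalling chain of the TCR complex, were stained with different oligonucleotide-tagged antibodies (hashtags), sorted into cells with only CD4 (CD4 single-positive, CD4 SP), only CD8 (CD8 SP) or both (double-positive, DP) on the surface, and loaded on the 10x Genomics 5′ platform, per the labels' protocols. Each RNA library therefore mixes both genotypes of 1 gate. The number of mice per genotype is not given in the sources used here, and each genotype was treated as 1 sample per gate.

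The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and barcode, with the hashtag counts in the same matrices. They were made with Cell Ranger 6.0.1 on GRCm38 (mm10), per the submitters' processing notes, while the matrix headers carry software version 3.1.0, per the file headers. Each matrix lists 31053 genes and 3 hashtags, and its barcodes were already limited to called cells, since the fewest UMIs in any barcode were 502. The deposited TCR tables give contigs with the UMI count behind each, and every contig listed is marked productive and in a called cell. Whether any other filter was used before deposit is not given in the sources used here.

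Hashtag 4 marks WT and hashtag 6 marks I173A, per the labels. Hashtag 5 is also in the matrices and has no genotype in the labels. The rule fixed in advance was for 1 hashtag against another; it was extended to all 3, so that a barcode took the hashtag with at least 10 counts and at least 4 times the counts of every other. Barcodes with several hashtags (4.20% in CD4 SP, 5.43% in CD8 SP and 5.72% in DP) were left out as doublets, and hashtag 5 cells entered no comparison between genotypes. Among barcodes called WT or I173A, Seurat's HTODemux (Seurat 5.3.0, R 4.3.3) gave the same call for 98.5%, 96.5% and 98.0%. Scrublet marked 1, 0 and 0 barcodes, a result that shows it did not work here, so doublets of 2 cells of the same genotype remain.

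Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. The 3 libraries were clustered together with Scanpy 1.11.5 and leidenalg 0.10.2 (counts scaled to 10000 UMIs per cell, 2000 variable genes without TCR and immunoglobulin segment genes, 30 principal components, 15 neighbours, Leiden resolution 1). Of 25 clusters, 19 were named "X-like" from marker genes fixed in advance and 6 stayed unnamed, for having fewer than 3 markers, more markers of another class among the 10 leading genes, or no matching set. These names were rebuilt from markers and are not the study's own. Clusters 9 and 20, high in the S phase gene Mcm5 but low in Mki67, stayed unnamed. Values given without cycling cells leave out only the cycling class and still include these clusters. Genes that define a cluster are not reported as findings within it.

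For each gate, UMIs were summed per genotype and divided by the group's total and given as CPM, with exact Poisson intervals. The ratio of I173A to WT carries the exact conditional interval for 2 Poisson counts, and shares of cells carry exact Clopper-Pearson intervals. All of these are 95% intervals and cover counting error only. With 1 sample per genotype and gate there is no replicate check, no test was run and no p-value is given, and no number of changed genes was taken from the cells. Words such as higher and lower describe these samples.

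The text names genes by a rule set before the data were examined. Per gate these were the 12 genes with the highest and the 12 with the lowest ratio, among genes with at least 200 UMIs and at least 20 CPM in 1 genotype whose interval left out 1; TCR and immunoglobulin segment, mitochondrial, ribosomal protein, haemoglobin and clone-named genes were left out. To these came 21 genes chosen in advance (among them Cd3e, Cd5, Cd69, Nr4a1, Egr1, Egr2, Pdcd1, Srebf1, Srebf2, Fasn, Scd1, Scd2, Cpt1a, Abca1, Abcg1, Rag1, Klf2, S1pr1 and Foxp3) and up to 4 members with the highest and 4 with the lowest ratio of each gene list. Coordinates come from the RefSeq annotation of GRCm38.p6, matched by symbol for 82 of the 85 genes named by ratio or always. Tgtp1 and Tgtp2, the H2 genes and the histone genes belong to families of similar sequence, and Dgkeos and Mir142hg are named for an antisense or host transcript, so how the counter split their reads is uncertain.

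In addition, 32 gene lists were fixed in advance for lipid pathways, TCR signalling, thymocyte stages and lineages, cell cycle, stress, interferon response and other cell types. A member entered with a mean of at least 5 CPM over both genotypes. Some lists share members. The negative selection and agonist, anergy and exhaustion, and regulatory T cell lists each share genes with the TCR signal list. Their medians are therefore not independent of it. Each list is summarised by its median log2 ratio, an order-statistic interval over its members, which are genes and not replicates, and the percentile of that median among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. For shares of cells with a UMI, each cell was thinned to 1500 UMIs, since 2000 would have kept under 80% of DP cells; this kept between 87.7% and 98.6% of cells per gate and genotype.

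Counts were simulated as Poisson draws from the real means. The ratio intervals held the true ratio for 95.4% of genes in CD4 SP, 95.5% in CD8 SP and 95.2% in DP. The intervals assume Poisson counts too, so this checks the computation and not the spread between cells or mice. Changes of 1.25-fold were recovered for 94%, 100% and 88% of 50 genes, and changes of 1.5-fold or more for 100% in each gate. Shifted lists all passed the 97.5th percentile, and unchanged lists fell outside the central range in 0%, 0% and 10% of 10 draws.

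Alternatives covered the hashtag rule, the cell filter, doublets, the scaling, the weight of each cell, thinning, the cells included, the expression floor of the lists, and the clustering; the closing section gives their effect. The CD3ε substitution cannot be read from 5′ counts per gene, so the counts do not check the genotype. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used.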

Results

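Single-cell RNA and TCR sequencing was carried out on thymocytes of WT and CD3ε I173A mice, sorted into CD4 SP, CD8 SP and DP cells. DP thymocytes rearrange the TCR α chain and are tested against self peptides on MHC molecules, and cells that pass mature into CD4 SP or CD8 SP cells. The 3 RNA libraries held 9081 barcodes in CD4 SP, 9239 in CD8 SP and 8670 in DP, with 60770018, 65934387 and 31269793 UMIs. After hashtag assignment and filtering, the CD4 SP gate had 3109 WT and 2664 I173A cells (20534690 and 16766444 UMIs), the CD8 SP gate 3017 and 2872 cells (22544044 and 17634074), and the DP gate 2516 and 2706 cells (10119851 and 8659807). Median UMIs per cell in WT and I173A were 6079 and 5786.5 in CD4 SP, 5704 and 5271.5 in CD8 SP, and 2906.5 and 2750.5 in DP. Each genotype was 1 sample per gate, so no difference below has a replicate check, and all intervals cover counting error only.

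The sort was first examined in WT cells. Zbtb7b, the transcription factor of the CD4 lineage, was at 108 CPM in the CD4 SP gate against 0.133 in CD8 SP and 1.68 in DP, and Cd40lg, a ligand of helper T cells, was at 149, 0.976 and 2.47 CPM. Nkg7, a granule protein gene of cytotoxic cells, was at 516 CPM in CD8 SP, 31.4 in CD4 SP and 0.593 in DP. The recombinase gene Rag1 was at 1049 CPM in DP, 7.65 in CD4 SP and 26.7 in CD8 SP. Klf2 and S1pr1, which govern exit from the thymus, were at 641 and 176 CPM in CD4 SP and 511 and 103 in CD8 SP, against 17.4 and 2.17 in DP. Mki67, a marker of proliferating cells, was at 732 CPM in DP, 288 in CD8 SP and 61.9 in CD4 SP. Cd4, Cd8a and Cd8b1 follow the sort itself and are no finding.

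The series title describes the substitution as one that enhances TCR signals, and the gene that carries it was examined first. Cd3e (ENSMUSG00000032093, chromosome 9, 44998735 to 45009663 in GRCm38) was at 1343 CPM in WT and 1443 in I173A CD4 SP cells, a ratio of 1.07 (interval 1.06 to 1.09). In CD8 SP it was at 1197 and 1440.3 CPM, a ratio of 1.20 (1.18 to 1.22), and in DP at 1366 and 1757 CPM, a ratio of 1.29 (1.26 to 1.32). Without cycling cells the ratios were 1.07, 1.06 and 1.12. A 5′ count of Cd3e covers both alleles and does not check the substitution.

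In the DP gate, the make-up of the population differed most in cycling cells, which made up a smaller share of I173A than of WT cells. Cycling cells were 15.5% of WT DP cells (391 of 2516, interval 14.1% to 17.02%) and 4.77% of I173A DP cells (129 of 2706, 4.00% to 5.64%), a ratio of 0.307 (0.249 to 0.375). Signalled-like cells were 5.33% of WT and 9.50% of I173A DP cells, a ratio of 1.78 (1.44 to 2.21); most were in cluster 10, which is high in Nr4a1, Egr1 and Cd5 and made up 4.69% and 8.57%. Rearranging DP-like cells were 73.5% and 82.8%. When the cells were clustered without the genes of the TCR signal and lipid lists, the ratios were 0.31 for cycling and 1.96 for signalled-like cells.

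The difference in cycling cells also appeared in single genes and in depth. After thinning each cell to 1500 UMIs, 18.1% of WT and 7.94% of I173A DP cells had an Mki67 UMI (25.0% and 12.4% before thinning); within rearranging DP-like cells, which are not in the cycling class, 5.85% and 4.78% had one. All 33 measured G2/M genes and all 30 measured S phase genes were lower in I173A DP cells, with median log2 ratios of -1.33 and -0.85. Among the genes with the lowest ratios were the spindle checkpoint kinase Bub1 (0.293, 0.241 to 0.354), citron kinase Cit, which acts in cytokinesis (0.260, 0.206 to 0.325), the kinetochore gene Cenpf (0.331, 0.304 to 0.360), the ubiquitin-conjugating enzyme Ube2c (0.329, 0.311 to 0.349), and Ankle1, Tmem97, Sgo1, Rad54b, Mastl, Kif14 and Diaph3, between 0.284 and 0.325. Cycling cells carry many UMIs and held 41.1% of the WT and 15.01% of the I173A DP UMIs, so a value summed over this gate depends on them.

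**Figure D1:**
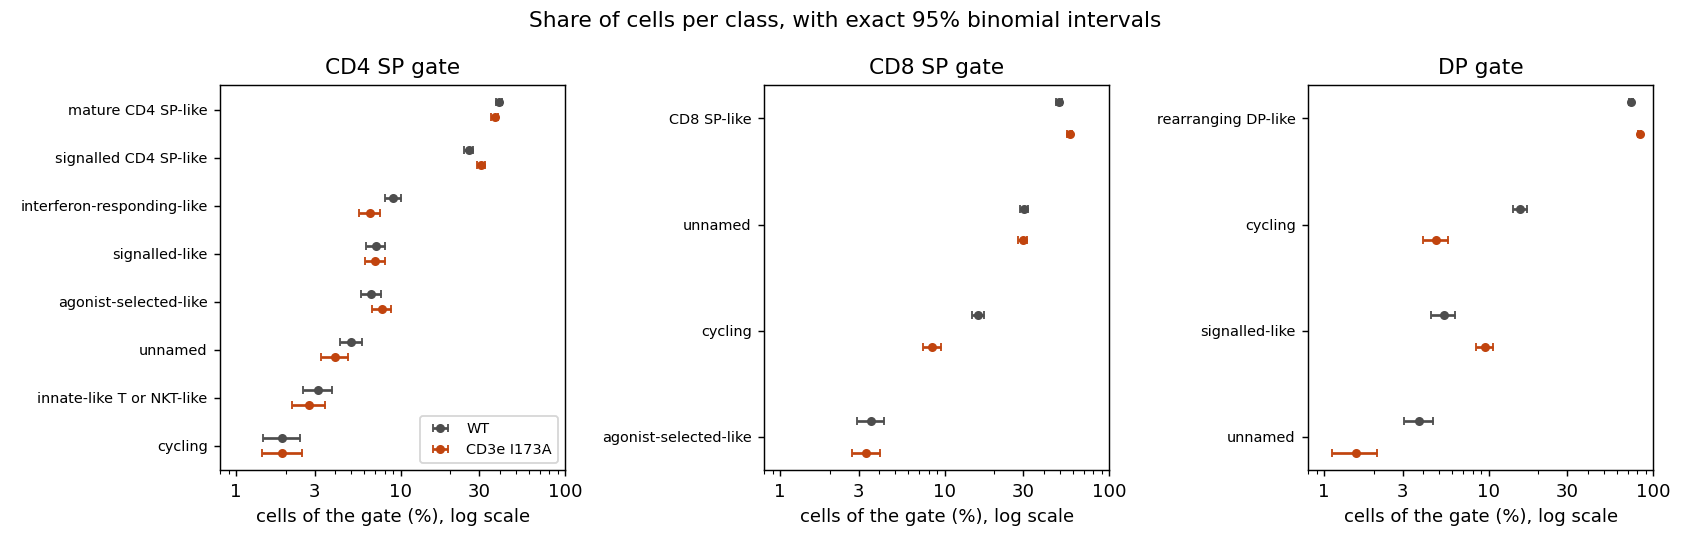
Share of cells per class in each gate (horizontal axis, percent of the gate's cells on a log scale) for WT and CD3ε I173A, with exact 95% binomial intervals that cover counting error only; classes under 1% in both genotypes are not drawn. In the DP gate cycling cells were 15.5% of WT and 4.77% of I173A cells, and signalled-like cells 5.33% and 9.50%.

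Genes of the response to TCR signals were higher in I173A DP cells. Of the 19 measured members of that list, 17 were higher, with a median log2 ratio of 0.51 (0.30 to 0.68 over its members), above all 10000 matched random lists. Cd5, a surface inhibitor whose level follows TCR signal strength, was at 182 and 290 CPM (ratio 1.60, 1.51 to 1.70), the nuclear receptor Nr4a1 at a ratio of 1.70 (1.46 to 1.97), the transcription factor Egr1 at 93.2 and 151 CPM (1.62, 1.49 to 1.76), and Nab2, a corepressor of the EGR factors, at 21.05 and 45.6 CPM (2.17, 1.83 to 2.57). Egr2 had a ratio of 1.44 (1.13 to 1.85), the inhibitory receptor Pdcd1 1.60 (1.15 to 2.24), Cd69 1.251 (1.11 to 1.41), a direction that turned without cycling cells, and Myc 0.639 (0.535 to 0.761). The list of negative selection and agonist markers had a median of 0.43, with 9 of 11 higher. The list of anergy and exhaustion genes was at 0.53, with 9 of 9 higher, among them Ctla4 (1.95, 1.39 to 2.75) and Lag3 (1.67, 1.20 to 2.33). Both lists share members with the TCR signal list, among them Nr4a1 and Pdcd1, so their medians are in part the same genes counted again.

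Most of the difference in the TCR signal list was lost when cycling cells were left out. Without cycling cells its median was 0.10, at the percentile 97.1 of random lists, and at equal cluster shares 0.11. Without cycling cells Cd5 had a ratio of 1.35 (1.26 to 1.44), Nr4a1 1.23 (1.05 to 1.43), Egr1 1.17 (1.07 to 1.28), Egr2 1.01 (0.787 to 1.30), Cd69 0.949 (0.837 to 1.08), Pdcd1 1.71 (1.14 to 2.62), Ctla4 1.60 (1.10 to 2.36) and Lag3 1.37 (0.972 to 1.95). The negative selection and agonist list was then at 0.10 (-0.30 to 0.45) and the anergy and exhaustion list at 0.27 (0.03 to 0.68). Within rearranging DP-like cells alone the TCR signal list was at 0.02, and the direction turned for Nr4a1 (log2 ratio -0.47) and Cd69 (-0.60). Signalled-like cells were named for high levels of these same genes. Keeping only rearranging DP-like cells, or setting equal cluster shares, therefore takes out part of a signal difference by construction. These 2 values cannot tell the make-up of the gate from a difference in signal. Genes of the TCR complex and its proximal kinases and adaptors had a median of 0.24 in the whole gate (26 of 29 higher, led by Cd28 at 1.39) and 0.03 without cycling cells.

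Apart from the TCR signal and cell cycle genes, the DP genes with the highest ratios were led by Cpt1a, described with the lipid genes. Ephx1, a microsomal epoxide hydrolase, was at 7.51 and 21.02 CPM (2.80, 2.13 to 3.71; 2.08 without cycling cells). Tsc22d3, a transcription regulator also called GILZ and induced by glucocorticoids, was at 99.0 and 223 CPM (2.26, 2.09 to 2.44; 1.88 without cycling cells). The heparan sulfate proteoglycan Sdc4 had a ratio of 2.14 (1.75 to 2.63), H2-Oa, which modulates peptide loading of MHC class II, 2.11 (1.73 to 2.57), and Prr29, Zfp945, Pacsin1, Tle2 and Myo1f between 1.97 and 2.15; without cycling cells Prr29 was at 1.93, H2-Oa at 1.65 and Tle2 at 1.39. Klf2 was lower in I173A DP cells (17.4 and 10.0 CPM, 0.578, 0.442 to 0.751; 0.471 without cycling cells). In the stress list, whose members respond to tissue dissociation and heat, 13 of 20 were lower (median log2 ratio -0.20; -0.23 without cycling cells, and -0.12 without cluster 22 and the low-RNA clusters): Jun had a ratio of 0.423 (0.376 to 0.476), Fos 0.350 (0.286 to 0.425), Fosb 0.257 (0.166 to 0.386) and the heat shock protein gene Hsph1 0.444 (0.356 to 0.552). Cluster 15, an unnamed cluster with a median of 1130.5 UMIs and 4.79% mitochondrial UMIs, with Jun among its leading genes, made up 3.54% of WT and 1.44% of I173A cells in DP, 1.03% and 0.450% in CD4 SP and 0.298% and 0.0348% in CD8 SP. Jun was lower within each of the 10 classes compared, none of which holds that cluster, with ratios from 0.288 to 0.449.

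The whole CD8 SP gate of I173A also held fewer cycling cells, and summed over all its cells TCR signal genes and maturation genes were higher. Cycling cells were 16.01% of WT (483 of 3017, 14.7% to 17.4%) and 8.43% of I173A cells (242 of 2872, 7.44% to 9.50%), a ratio of 0.526 (0.449 to 0.615), and they held 35.8% and 17.7% of the UMIs. The clusters behind this differed. Cluster 8 made up 6.66% and 1.32% and cluster 13 3.35% and 1.15% of cells. Cluster 11 made up 4.44% and 4.04% and cluster 19 1.09% and 1.60%. Clusters 8, 13, 16 and 23, which also held the cycling cells of the DP gate, together made up 10.5% and 2.79% (0.266, 0.205 to 0.341). The lower share was thus not one of all cycling clusters, and was not shown for mature CD8 SP cells. CD8 SP-like cells were 49.6% of WT and 57.6% of I173A cells (1.16, 1.08 to 1.246). The S phase and G2/M lists had medians of -0.74 and -0.75, with none of their 30 and 33 members higher. Without cycling cells they were at -0.23 (25 of 28 lower) and -0.07. The unnamed cluster 9, which stays in those values, made up 7.66% of WT and 6.02% of I173A cells (0.787, 0.642 to 0.962).

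The lowest ratios in the CD8 SP gate belonged to genes of earlier thymocyte stages. Ptcra, the α chain of the pre-TCR, was at 32.8 and 6.12 CPM (0.187, 0.151 to 0.229), Rag1 at 26.7 and 7.49 CPM (0.280, 0.230 to 0.339), and Dntt, the polymerase that adds nucleotides at V(D)J joints, at 218 and 72.0 CPM (0.330, 0.310 to 0.351). Arpp21, Endou, Dgkeos, Nebl and Nt5dc2 lay between 0.245 and 0.329, and the cell cycle transcription factors Mybl2 and E2f8 at 0.337 and 0.355. The list of genes of rearranging DP cells had a median log2 ratio of -0.99, with 15 of 16 lower. These genes sat with the cycling cells. Without cycling cells the list median was -0.08 over the 9 members then measured. Dntt had a ratio of 1.08 (0.891 to 1.31), and Endou one of 1.90 (0.839 to 4.57).

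Genes of later stages and of TCR signals were higher in the I173A CD8 SP gate. In the list of maturation and egress, 22 of 23 members were higher (median 0.30), including the survival gene Bcl2 (1.504, 1.44 to 1.57), the IL-7 receptor gene Il7r (1.49, 1.42 to 1.56), Klf2 (1.35, 1.32 to 1.39) and S1pr1 (1.22, 1.15 to 1.29), but without cycling cells the median was -0.02 and the direction of S1pr1 turned (log2 ratio -0.07). The TCR signal list had a median of 0.36 (24 of 27 higher) and 0.12 without cycling cells; Nr4a1 was at 34.6 and 59.3 CPM (1.71, 1.56 to 1.88; 1.35 without cycling cells), Nr4a3 at a ratio of 1.62 (1.26 to 2.09), Cd83 at 1.77 (1.33 to 2.36) and Cd5 at 1.33 (1.27 to 1.39; 1.09 without cycling cells). The negative selection and agonist list, which shares members with the TCR signal list, had a median of 0.42 (0.21 without cycling cells). The TCR complex list had a median of 0.18 (25 of 30 higher, and 0.03 without cycling cells). The CD8 lineage list was at 0.38 (9 of 11 higher; 0.05 without cycling cells), with the IL-2 receptor chain Il2rb at 1.54 (1.45 to 1.63). Cd69, Egr1 and Egr2 had ratios of 0.956, 1.26 and 1.18 (0.748, 1.00 and 0.899 without cycling cells, where the direction of Egr2 turned), and Pdcd1 1.17 (0.969 to 1.41).

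Among the CD8 SP genes with the highest ratios, 4 belonged to antigen presentation by MHC class II. H2-Aa was at 0.754 and 25.5 CPM (33.8, 20.9 to 58.5), H2-Eb1 at 0.798 and 24.8 CPM, H2-Ab1 at 2.48 and 27.3 CPM and the invariant chain Cd74 at 21.4 and 104 CPM. Only 7 cells of each genotype in this gate were macrophage or dendritic-like, and without that cluster and the low-RNA clusters the log2 ratio of H2-Ab1 was -1.43 and that of H2-Eb1 -0.45. The others were Cpt1a, Tsc22d3 (80.1 and 214 CPM, 2.67, 2.53 to 2.83), Ddit4, an inhibitor of mTORC1 signalling (134 and 314 CPM, 2.35, 2.25 to 2.46), the receptor Gpr83 (1.97, 1.68 to 2.31), the aquaglyceroporin Aqp3 (1.87, 1.59 to 2.20), Crybg1 (1.85, 1.65 to 2.08), the cytokine-induced suppressor Cish (1.84, 1.58 to 2.15) and Prag1 (1.77, 1.53 to 2.05). In the stress list 12 of 19 were lower (median -0.19), with Jun at 0.363 (0.315 to 0.418) and Hsph1 at 0.495 (0.449 to 0.546).

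The CD4 SP gate differed less in its make-up. The cycling class made up 1.90% of WT and 1.91% of I173A cells. The unnamed cluster 20, high in Mcm5 and not in that class, made up 1.93% and 1.01% (0.525, 0.321 to 0.840). Signalled CD4 SP-like cells were 25.9% and 31.0% (1.19, 1.08 to 1.32), interferon-responding-like cells 9.04% and 6.49% (0.719, 0.591 to 0.871), agonist-selected-like cells 6.63% and 7.66% (1.16, 0.948 to 1.41), mature CD4 SP-like cells 39.8% and 37.5% and signalled-like cells 7.04% and 7.02%. The last class joins cluster 18, high in Egr2, Egr1 and Nr4a1 (3.41% and 2.55%, 0.749, 0.544 to 1.02), and cluster 12, which is high in Ccr9 and Tox but low in Nr4a1 and Cd5 (3.51% and 4.35%, 1.24, 0.948 to 1.63). The agonist-selected-like ratio turned to 0.891 when the TCR signal and lipid genes were left out of the clustering. The S phase and G2/M lists were at -0.18 and -0.10. Without cycling cells they were at -0.22 (21 of 23 lower) and -0.02.

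TCR signal genes split in the CD4 SP gate. Nr4a1 was at 151 and 227 CPM (1.502, 1.43 to 1.58), Pdcd1 at 19.4 and 31.4 CPM (1.62, 1.42 to 1.85), Nfkbid, an inhibitor protein of NF-κB, at 61.6 and 84.6 CPM (1.37, 1.27 to 1.48), Gadd45b at a ratio of 1.39 (1.20 to 1.60) and Cd5 at 1.11 (1.08 to 1.14). The immediate early genes of the EGR family were lower, with Egr1 at 0.933 (0.894 to 0.974), Egr2 at 0.840 (0.760 to 0.928) and Egr3 at 0.661 (0.492 to 0.881), as was Myc (0.812, 0.765 to 0.862), and Cd69 was at 0.958 (0.910 to 1.01). The list had a median of 0.19, with 17 of 26 higher. Markers of negative selection and agonist selection were at 0.41 (13 of 15 higher, above all 10000 random lists), including the TNF receptor family gene Tnfrsf18 (1.40, 1.33 to 1.48). All 11 measured regulatory T cell genes were higher (median 0.34), led by Il2ra (1.53, 1.27 to 1.85); Foxp3, the lineage factor of regulatory T cells, lay under the floor for the list at 5.55 and 4.17 CPM (0.752, 0.550 to 1.02). The anergy and exhaustion list was at 0.16 and the TCR complex list at 0.02. The negative selection, regulatory T cell and anergy lists share members with the TCR signal list and are not separate results.

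The CD4 SP genes with the highest ratios were Cpt1a, Tsc22d3 (86.2 and 196 CPM, 2.27, 2.14 to 2.41), Ddit4 (172.9 and 372 CPM, 2.15, 2.06 to 2.24), the sialyltransferase St6galnac3 (2.01, 1.73 to 2.35) and Bbc3, which encodes the apoptosis inducer PUMA (13.4 and 26.5 CPM, 1.98, 1.70 to 2.31). Hist1h3b, the calmodulin-binding Nrgn, Itih5, Klhdc2, the surface peptidase Dpp4 and Mir142hg lay between 1.52 and 1.85. The lowest were Jun (43.3 and 15.9 CPM, 0.366, 0.318 to 0.420) and Hsph1 (46.8 and 18.01 CPM, 0.385, 0.337 to 0.439), in a stress list at -0.20 with 12 of 19 lower. Lower too were Tgtp1 (0.582, 0.522 to 0.648) and Tgtp2 (0.663, 0.613 to 0.718), GTPases induced by interferon, H2-Q7, an MHC class I gene (0.683, 0.641 to 0.726), the chemokine receptor Cxcr6 (0.659, 0.558 to 0.777), and Ahnak, Amigo2, Ly6k, Hist1h2ac, Banp and Prrg1 between 0.569 and 0.668. Within mature and signalled CD4 SP-like cells alone the direction turned for Cxcr6 (log2 ratio 0.24) and Hist1h3b (-0.17), and Ahnak was at 0.00.

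The interferon response was lower in the I173A CD4 SP gate: 19 of 20 measured members had a ratio below 1, with a median log2 ratio of -0.22 (-0.30 to -0.16) and Ifit3 at 0.699 (0.612 to 0.798). The list was higher in the CD8 SP gate, with 21 of 21 members above 1 and a median of 0.36, which was 0.05 without cycling cells. In DP it was at 0.20, and -0.04 without cycling cells. Maturation and egress genes were at -0.06 in CD4 SP, with S1pr1 at 0.837 (0.795 to 0.882) and Klf2 at 0.958 (0.934 to 0.983).

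Lipid metabolism is named in the series title, and the clearest lipid gene was Cpt1a, the enzyme that commits long-chain fatty acids to import into mitochondria for oxidation. Cpt1a (ENSMUSG00000024900, chromosome 19, 3322326 to 3385735 in GRCm38) was higher in I173A cells of all 3 gates. In CD4 SP it was at 8.72 CPM (7.49 to 10.1; 179 UMIs) in WT and 40.1 CPM (37.1 to 43.2; 672 UMIs) in I173A, a ratio of 4.60 (3.89 to 5.45). In CD8 SP it was at 10.0 CPM (8.76 to 11.4) and 28.6 CPM (26.1 to 31.2), a ratio of 2.85 (2.43 to 3.35; 3.51 without cycling cells), and in DP at 11.3 CPM (9.29 to 13.5) and 52.9 CPM (48.2 to 58.0), a ratio of 4.69 (3.82 to 5.82; 6.32 without cycling cells). It was the gene with the highest ratio in CD4 SP and in DP under the rule for named genes. Within each of the 10 classes compared it was also higher in I173A, with ratios from 2.55 in cycling CD8 SP cells (1.95 to 3.34) to 11.3 in agonist-selected-like CD8 SP cells, where only 1 and 10 UMIs were counted.

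**Figure D2:**
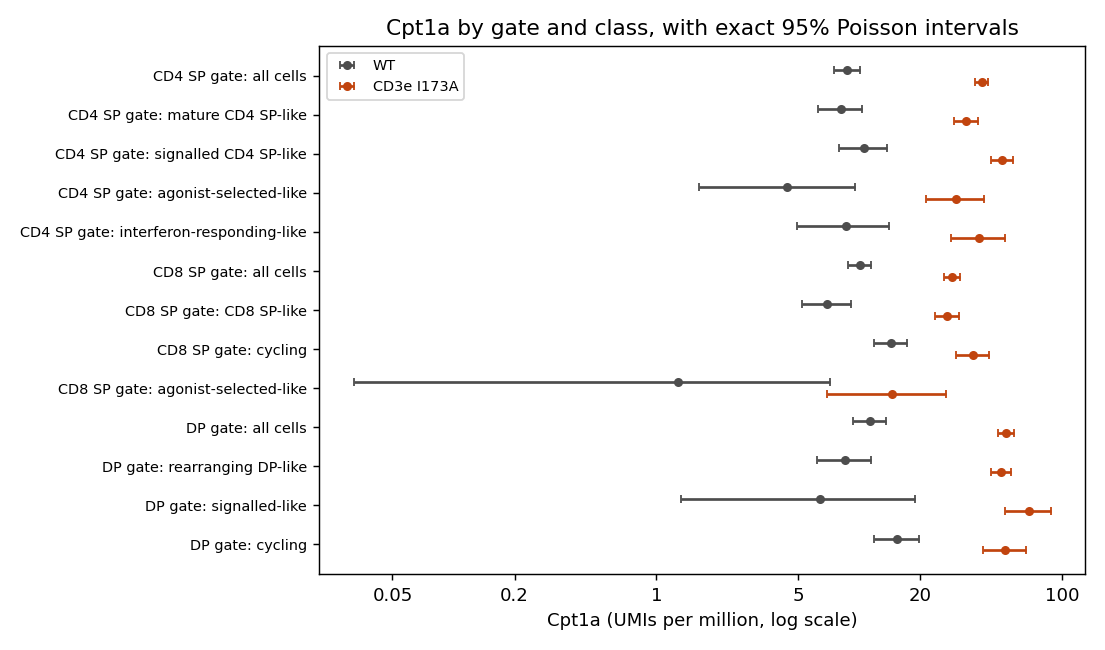
Cpt1a in CPM (horizontal axis, log scale) in WT and CD3ε I173A cells, in all cells of each gate and in each class compared, with exact 95% Poisson intervals that cover counting error only. The I173A value lies above the WT value in every line, at 40.1 against 8.72 CPM in the whole CD4 SP gate and 52.9 against 11.3 in the whole DP gate.

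Other genes of fatty acid oxidation were higher by less. Slc25a20, which carries acylcarnitines across the inner mitochondrial membrane, had ratios of 1.42 (1.26 to 1.60) in CD4 SP, 1.57 (1.38 to 1.79) in CD8 SP and 2.01 (1.69 to 2.39) in DP. Acadvl, the dehydrogenase of very long chain acyl-CoA, had ratios of 1.31, 1.28 and 1.77 (1.56 to 2.00), and the thiolase Acaa2 1.32 (1.24 to 1.40) in CD4 SP and 1.33 (1.23 to 1.43) in DP. Cpt2, which acts after Cpt1a on the inner membrane, was at 1.01 in CD4 SP and 1.01 in DP, and Etfa at 0.883 (0.830 to 0.940) in CD8 SP and 0.904 (0.821 to 0.995) in DP. In the list, 17 of 19 members were higher in CD4 SP, 14 of 19 in CD8 SP and 16 of 19 in DP, with medians of 0.14 (0.10 to 0.22 over the members), 0.12 (-0.04 to 0.23) and 0.21 (0.02 to 0.38), at the percentiles 99.7, 93.0 and 98.4 of random lists. Without cycling cells the medians were 0.14, 0.19 and 0.13.

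Genes of cholesterol synthesis were lower in I173A cells of the CD8 SP and DP gates, and mainly in cycling cells. In the whole CD8 SP gate 17 of 20 members were lower (median -0.34, -0.68 to -0.20), led by the squalene epoxidase Sqle (11.2 and 2.21 CPM, 0.197, 0.137 to 0.277), Idi1 (0.305, 0.258 to 0.359) and Fdps (0.453, 0.413 to 0.497). In DP 14 of 19 were lower (median -0.19, -0.38 to 0.09), led by Cyp51 (0.487, 0.366 to 0.644), Idi1 (0.556, 0.453 to 0.679) and Sqle (0.594, 0.429 to 0.815), and in CD4 SP 5 of 17 (median 0.10, -0.01 to 0.12). Without cycling cells the CD8 SP and DP medians were -0.00 and 0.05. Within cycling cells the list was at -0.87 in CD8 SP, with 16 of 19 members lower, and at -0.44 in DP, with 15 of 18 lower; in the CD8 SP gate, clusters 8 and 13 made up more of the WT than of the I173A cycling cells.

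Single genes of sterol regulation were examined next. Insig1, which holds back the sterol sensor, was at 0.397 (0.310 to 0.504) in CD8 SP and 0.640 (0.527 to 0.775) in DP, where it stayed at 0.585 (0.462 to 0.739) without cycling cells. The transcription factor genes Srebf1 (1.08, 1.02 and 0.987 in CD4 SP, CD8 SP and DP) and Srebf2 (1.02, 0.793 and 0.918) differed less. Srebf2 was at 1.01 in CD8 SP without cycling cells. The sterol regulation and uptake list as a whole was at 0.03, 0.06 and 0.04.

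Cholesterol efflux genes, targets of the oxysterol receptor LXR, were at medians of 0.06 in CD4 SP, 0.22 in CD8 SP and 0.21 in DP, and at 0.07, 0.03 and 0.06 without cycling cells. The exporters Abca1 and Abcg1 went apart in DP: Abca1 was at 24.9 and 40.9 CPM (1.64, 1.39 to 1.94; 1.14 without cycling cells), and Abcg1 at 114 and 94.2 CPM (0.827, 0.755 to 0.905; 0.645 without cycling cells). In CD4 SP Abcg1 was at 0.770 (0.718 to 0.825) and Abca1 at 1.03 (0.917 to 1.15). Fatty acid synthesis genes were at -0.04, -0.01 and -0.05, with Fasn at 0.895, 0.759 (0.683 to 0.843) and 0.965, and Scd2 at 0.972, 0.783 (0.719 to 0.852) and 0.764 (0.704 to 0.830); Scd1 had almost no UMIs. Lipid uptake, storage and lipolysis genes were at 0.04, 0.00 and 0.30, and 0.13 in DP without cycling cells. In DP, 10 of 12 were higher, including the lipid droplet coat protein Plin2 (47.1 and 81.9 CPM, 1.74, 1.54 to 1.95) and Hilpda, which inhibits lipolysis (1.73, 1.46 to 2.04), while the fatty acid binding protein gene Fabp5 was lower (0.574, 0.489 to 0.673); without cycling cells they were at 1.39, 1.51 and 0.967. Phospholipid and sphingolipid synthesis genes were at 0.06, 0.06 and 0.13, and at 0.06, 0.00 and 0.07 without cycling cells.

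**Figure D3:**
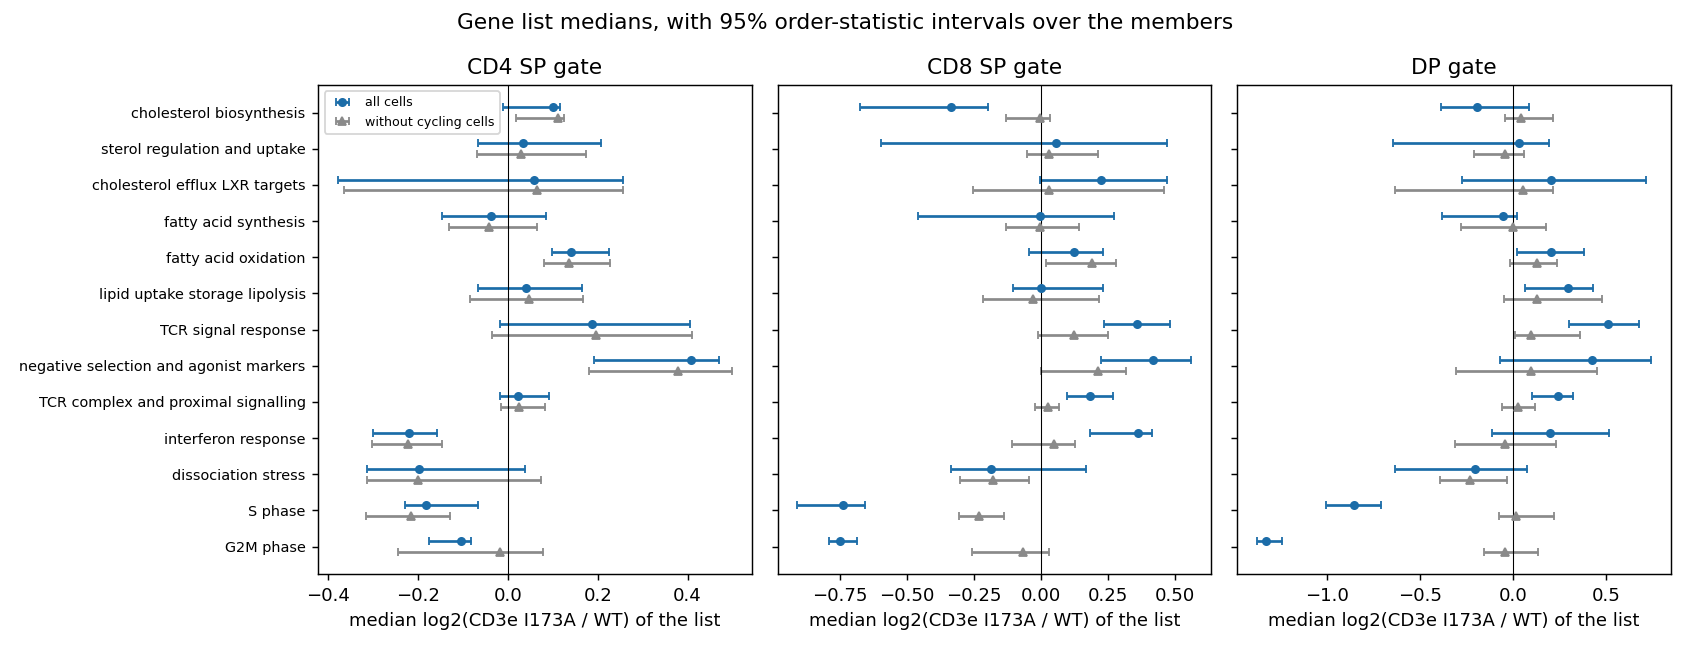
Median log2 ratio of I173A to WT (horizontal axis) of 13 gene lists in each gate, over all cells (circles) and without cycling cells (triangles), with 95% order-statistic intervals over the list's genes. The TCR signal list in DP lies at 0.51 with all cells and 0.10 without cycling cells, and the fatty acid oxidation list in CD4 SP at 0.14 in both.

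Metabolic and stress lists outside lipids were mostly lower. Glycolysis genes had medians of -0.00 in CD4 SP, -0.10 in CD8 SP and -0.15 in DP (-0.00, -0.04 and -0.09 without cycling cells), with the triosephosphate isomerase Tpi1 at 0.897, 0.574 (0.537 to 0.613) and 0.463 (0.403 to 0.529), and at 0.966 in CD8 SP and 0.791 in DP without them. Nuclear genes of oxidative phosphorylation were at 0.02, -0.14 and -0.08 (0.02, -0.01 and -0.03 without cycling cells), with 22 of 23 lower in CD8 SP and cytochrome c, Cycs, at 0.915, 0.717 and 0.795. In the list of unfolded protein and integrated stress responses (-0.19, -0.08 and -0.15; -0.19, -0.13 and -0.01 without cycling cells), the serine synthesis gene Psat1 had ratios of 0.798 (0.718 to 0.888), 0.688 (0.630 to 0.752) and 0.489 (0.404 to 0.590), and Sdf2l1, of the endoplasmic reticulum chaperones, 0.702, 0.664 and 0.543; without cycling cells Psat1 was at 0.901 in CD8 SP and 0.739 in DP, and Sdf2l1 at 0.743 and 0.811. Apoptosis and p53 genes were at 0.06, 0.13 and 0.20, and without cycling cells at 0.07, 0.08 and -0.03, so the direction turned in DP. The death receptor gene Fas had ratios of 1.22, 1.22 and 1.27 (1.02 in CD8 SP and 1.02 in DP without cycling cells), Zmat3 2.02 (1.54 to 2.66) in DP (1.49) and the BH3-only gene Bid 0.666 in CD8 SP and 0.647 in DP (1.06 and 0.805).

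Lists of thymocyte stages and lineages completed the comparison. Rearranging DP genes were at 0.12 in CD4 SP and 0.15 in DP, where 16 of 17 were higher, but 14 of 17 were lower without cycling cells (-0.08, -0.12 to -0.03). Maturation and egress genes were at 0.19 in DP and -0.07 without cycling cells. Markers of immature SP cells were at 0.12, -0.10 and 0.29 (0.13, -0.09 and -0.02 without cycling cells), with Ly6d at 2.68 (2.21 to 3.28) in CD4 SP and 0.437 (0.411 to 0.463; 0.892 without cycling cells) in CD8 SP. The CD4 lineage list was at 0.09, 0.23 and 0.30 (0.09, -0.00 and -0.03 without cycling cells), and the CD8 lineage list at 0.20 in CD4 SP and 0.18 in DP (0.22 and 0.01). The regulatory T cell list was at 0.40 in CD8 SP and 0.43 in DP (0.10 and 0.08 without cycling cells), and the anergy and exhaustion list at 0.26 in CD8 SP (0.06). Genes of innate-like and NKT cells were at -0.08 in CD4 SP, with the chemokine Ccl5 at 0.474 (0.374 to 0.596) and the lineage factor Zbtb16 at 1.39 (1.05 to 1.83), and at 0.21 in CD8 SP; without cycling cells they were at -0.28 (8 of 10 measured lower) and 0.00. Macrophage and dendritic genes were at 3.46 in CD8 SP, over 5 measured members, and at 1.44 in DP, over 3 (2 higher and 1 lower). Stromal genes were at 0.21, 0.12 and 0.30 over 3 measured members in each gate (0.20, -0.09 and 0.11 without cycling cells). Both lists had too few measured members for an interval. The B cell, γδ T cell, erythroid and platelet, and NK and granulocyte lists had at most 2 measured members in any gate.

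The TCR tables were used to compare chain recovery and repertoire. A productive α chain is made at the DP stage, and paired chains were seen in more I173A than WT DP cells: 34.4% (930 of 2706, 32.6% to 36.2%) against 27.1% (681 of 2516, 25.3% to 28.8%), a ratio of 1.27 (1.15 to 1.40). Productive β chains were found in 81.6% and 79.3%. Within rearranging DP-like cells the paired shares were 30.4% in I173A and 27.8% in WT (1.09, 0.972 to 1.23), and within signalled-like cells 79.0% and 70.1% (1.13, 0.878 to 1.45). In CD8 SP, pairs were found in 81.3% of I173A and 76.5% of WT cells; within cycling CD8 SP cells they were found in 63.2% and 35.8% (1.77, 1.41 to 2.21). These cells sat in different clusters, with 38 of 242 I173A and 201 of 483 WT cycling cells in cluster 8. Within CD8 SP-like cells they were found in 82.8% and 85.1%. CD4 SP cells had pairs in 87.8% and 87.7%.

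Repertoire measures differed little between the genotypes. The share of α chains with a J segment numbered 40 or above, which are used first, was 39.1% in WT and 36.3% in I173A DP cells, 23.6% and 25.6% in CD4 SP and 26.7% and 27.8% in CD8 SP, each with a ratio interval that includes 1. Hydrophobic residues at position 6 or 7 of the β chain CDR3, the loop that contacts the peptide, were found in 25.0% and 26.3% of CD4 SP, 26.9% and 25.3% of CD8 SP and 21.4% and 23.8% of DP chains. Mean CDR3 lengths of the β chain were 13.8 and 13.8 residues in CD4 SP, 13.9 and 13.9 in CD8 SP and 14.2 and 14.2 in DP. A second α chain was held by 14.98% and 13.9% of CD4 SP, 13.6% and 13.2% of CD8 SP and 8.14% and 10.3% of DP cells with an α chain. The invariant TRAV11 with TRAJ18 chain of NKT cells was in 45 of 2770 WT and 37 of 2373 I173A CD4 SP cells (1.62% and 1.56%).

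Of the V genes that made up at least 1% of the chains of either genotype, the ratio interval left out 1 for 1 of 43 α and 1 of 20 β genes in CD4 SP, 2 of 42 and 1 of 20 in CD8 SP, and 5 of 45 and 3 of 20 in DP. In DP, TRBV13-1 was 5.26% of WT and 7.09% of I173A β chains (1.35, 1.05 to 1.74), TRBV13-2 1.36% and 2.58% (1.89, 1.19 to 3.08) and TRBV31 5.11% and 3.46% (0.676, 0.498 to 0.913). Paired CDR3s that recurred in several cells were rare. They were in 16 of 2728 WT and 2 of 2339 I173A CD4 SP pairs (ratio 0.146). In CD8 SP they were in 8 of 2309 and 4 of 2335 pairs, and in DP in 4 of 681 and 10 of 930 pairs. Cells that share a pair are not independent counts, so no interval is given for these ratios.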

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

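Both tests of cluster shares behind the interferon response were chosen after the result was seen. In the CD4 SP gate the interferon response genes were lower in I173A cells (median log2 ratio -0.22, 19 of 20 members lower), and in the CD8 SP gate they were higher (0.36, 21 of 21 higher), so the gates point opposite ways; this difference between gates was not tested. Within mature and signalled CD4 SP-like cells, the classes that the CD4 SP gate is named for, the median was -0.15 (-0.28 to -0.06). The lower median therefore did not rest on the fewer interferon-responding-like cells alone. The mix of these classes also differed, with signalled CD4 SP-like cells at 25.9% of WT and 31.0% of I173A cells. Different cluster shares thus stay open as a cause there. Within CD8 SP-like cells the median was 0.0203 (-0.21 to 0.13), and 0.05 over the whole gate without cycling cells, the values that different cluster shares need. A smaller share of cycling cells may therefore account for the CD8 SP median. An effect of genotype in the CD4 SP gate stays open and untested, since genotype and sample are the same thing in this design.

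Genes of rearranging DP cells also went opposite ways, at -0.99 in the CD8 SP gate and 0.15 in the DP gate. This difference was not tested. Without cycling cells the medians were -0.08 in each of these gates. In CD8 SP only 9 members were then measured (4 higher and 5 lower, -0.18 to 0.11), against 16 over all cells. The medians with and without cycling cells therefore cover different genes there.

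Hashtag 5, to which the labels give no genotype, was called for 31.4% of CD4 SP, 30.1% of CD8 SP and 32.5% of DP barcodes, a signal in data that no comparison above uses, with its own cells described under the other observations.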

How the results depend on the processing

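The hashtag minimum of 50 counts, the removal of the highest 5% of doublet scores and the removal of cluster 22 with the low-RNA clusters were chosen after the data were seen. Over 21 settings, 2517 of 2892 recomputed values stayed within the interval of the reported value. Among single genes 227 values moved and 40 reversed, and among the lists outside the main questions 71 moved and 20 reversed. A value counted as reversed only where the reported interval left out no change. Elsewhere a value could turn and stay within the interval. The cholesterol synthesis median in DP did so, from -0.19 to 0.05 without cycling cells. Every planned setting was run; lists with fewer than 6 measured members were not included. No paired analysis was possible because no replicate numbers link the genotypes and each genotype is 1 sample per gate, and for the same reason leaving out each sample in turn was impossible. Values below are log2 ratios unless said otherwise, with the reported value in brackets, and beyond the cells each setting leaves out, the cause was not tested.

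Cpt1a and Tsc22d3 in every gate, Ddit4 in CD4 SP and CD8 SP and Jun in CD4 SP reversed under none of the settings they were computed for. The fatty acid oxidation list moved only in CD4 SP, under median-ratio scaling (0.0901 [0.14]), a setting that moved the median of all genes by -0.05, -0.04 and -0.09. Of the shares of cells, 1 moved. Clustered without the TCR signal and lipid genes, the ratio of the agonist-selected-like share in CD4 SP was 0.891 [1.16]. At Leiden resolution 0.5 no CD4 SP cells fell in a cluster matched to the interferon-responding-like class, so that share has no value there.

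Thinning and equal weight for each cell moved or reversed further values. With each cell thinned, Abca1 was at -0.0131 [0.22] and Egr2 at -0.43 [0.23] in CD8 SP, Cd69 at -0.23 [0.32] in DP, and Rag1 at -0.0604 [0.44] in CD4 SP and -0.0291 [0.23] in DP. The TCR signal list was at 0.11 [0.36] in CD8 SP and 0.22 [0.51] in DP, and the cholesterol synthesis list at 0.18 [0.10] in CD4 SP and -0.15 [-0.34] in CD8 SP. With the mean of per-cell CPM, Cd69 in DP was at -0.15, Egr2 in CD8 SP at -0.15, and Rag1 at -0.25 in CD4 SP and -0.0154 in DP; the TCR signal list was at 0.21 in CD8 SP and 0.28 in DP, and cholesterol synthesis in CD8 SP at -0.18.

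Leaving out cycling cells changed the make-up of the sums by construction. In CD8 SP this put Abca1 at -0.14, Arpp21 at 0.11 [-1.91], Dgkeos at 0.29 [-2.03], Dntt at 0.11 [-1.60], Egr2 at -0.15, Endou at 0.92 [-1.79], Rag1 at 1.48 [-1.83], S1pr1 at -0.0664 [0.28] and Srebf2 at 0.0166 [-0.33], with TCR signal at 0.12, cholesterol synthesis at -0.00406 and maturation at -0.0184 [0.30]. In DP it put Bub1 at 0.19 [-1.77], Cd69 at -0.0755 and Rag1 at -0.13, with TCR signal at 0.10, CD4 lineage at -0.0277 [0.30], rearranging DP at -0.0810 [0.15], immature SP at -0.0203 [0.29], maturation at -0.0740 [0.19] and S phase at 0.0197 [-0.85].

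With only the classes each gate is named for, CD4 SP had Ahnak at 0.00361 [-0.81], Cxcr6 at 0.24 [-0.60], Hist1h3b at -0.17 [0.89], Rag1 at -2.217 and G2/M at 0.0523 [-0.10]. CD8 SP had Abca1 at -0.12, Cd74 at -0.38 [2.28], H2-Aa at -0.69 [5.08], H2-Eb1 at -0.69 [4.96], Dntt at 0.0468, Egr2 at -0.26, Endou at 0.38, Nebl at 0.38 [-1.60] and Rag1 at 0.89, with TCR signal at 0.11, cholesterol synthesis at -0.0348, G2/M at 0.0317 [-0.75], maturation at -0.0424 and oxidative phosphorylation at 0.00636 [-0.14]. DP had Bub1 at 0.29, Cd69 at -0.60, Nr4a1 at -0.47 [0.76] and Rag1 at -0.0941, with TCR signal at 0.0223, CD4 lineage at -0.0126, rearranging DP at -0.0573, immature SP at -0.0715 and S phase at 0.0579.

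With both genotypes weighted to the same cluster shares, TCR signal was at 0.14 in CD8 SP and 0.11 in DP, immature SP at -0.0230 [0.12] in CD4 SP and -0.0229 in DP, rearranging DP at -0.0496 in DP, S phase at 0.0930 in DP, and G2/M at 0.00917 and maturation at -0.000665 in CD8 SP. Without cluster 22 and the low-RNA clusters, H2-Ab1 was at -1.43 [3.46] and H2-Eb1 at -0.45 in CD8 SP.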

Other observations

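The tests of Cpt1a within classes and of the expected number of doublets were chosen after the result was seen, and the removal of high doublet scores after the data but before its own result; the hashtag, glucocorticoid and PPAR tests were set before their results. Cells with hashtag 5 had Cpt1a at 8.48 CPM in CD4 SP, 8.73 in CD8 SP and 10.5 in DP, Tsc22d3 at 108, 99.2 and 121 CPM, Ddit4 at 234, 175 and 149 CPM, and Jun at 39.8, 34.7 and 106 CPM. Their Nr4a1 was at 197, 46.7 and 49.1 CPM and Cd5 at 594, 184 and 249.6 CPM. Cycling cells were 11.8% and signalled-like cells 7.20% of hashtag 5 cells in DP, cycling cells 14.4% in CD8 SP and interferon-responding-like cells 10.99% in CD4 SP.

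Cpt1a was higher in I173A cells of every gate, with ratios of 4.60 in CD4 SP, 2.85 in CD8 SP and 4.69 in DP. A different mix of cell classes is excluded as the whole cause, since the smallest ratio over the 10 classes compared was 2.55 (1.95 to 3.34) and every interval lay above 1. More glucocorticoid in the I173A sample, as the ratios of Tsc22d3 might point to, stays open. The other target genes of the glucocorticoid receptor had medians of 0.23, 0.13 and 0.22, at the percentiles 99.7, 81.8 and 91.4 of random lists. Among them, Cxcr4 was at 2.66 (2.06 to 3.45) in CD4 SP and Fkbp5 at 0.784 (0.729 to 0.844) in CD8 SP. Without cycling cells Fkbp5 was at 1.35 (1.20 to 1.53) in CD8 SP, where 9 of 9 targets were higher, and the medians were 0.27, 0.19 and 0.10, at the percentiles 99.9, 98.4 and 85.3 of random lists. Higher activity of PPAR, a receptor family that drives Cpt1a, stays open too, with medians of 0.23, 0.0822 and 0.20 over its other targets, at the percentiles 99.9, 71.3 and 88.4 of random lists, and 0.22, 0.10 and 0.11 without cycling cells, at 99.9, 88.8 and 93.4. A genotype effect, and any other difference between the animals, also stay open and untested.

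Cycling cells made up less of the I173A than of the WT DP gate. The choice of hashtag rule made little difference, as the ratio of the shares was 0.298 with the HTODemux calls and 0.296 with a 10-fold hashtag rule. The ratio as reported was 0.307. All these rules use the same hashtag counts, and the barcodes left out for several hashtags or none were not examined. A loss of cycling cells in hashtag calling therefore stays open. Doublets formed at random in the droplets are excluded as the whole cause. At most 7.70% of DP barcodes held several hashtags under any of the hashtag rules. With the upper bound of that share, 108 WT and 123 I173A doublets of cells with the same hashtag would be expected; taking these out of the WT cycling cells and out of the other I173A cells left a ratio of 0.425 (0.342 to 0.525). Among 1500 UMIs per cell, where doublets of cells that do not cycle would not raise it, the share of cells with an Mki67 UMI had a ratio of 0.439 (0.368 to 0.523). The ratio of 0.309 without the 5% of cells with the highest doublet scores decides nothing, as Scrublet called no doublet in this library. Clumps that formed before the samples were pooled and hold a cycling cell stay open and untested. A difference in the sorting of large cells could not be examined, and a genotype effect stays open and untested.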
